A study of Mus musculus with 45 samples.

How the data were processed

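Acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse hippocampus. The series holds 45 libraries. The 23 H3K9ac libraries were analysed here, and the 22 libraries of input DNA have no column in the deposited count matrix. Each library was placed in its group by its label, and 0 count columns were left without a matching sample.

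The deposited values are raw read counts per domain, with no normalization, for 44165 domains shared by all libraries. Per the submitters' processing notes, BWA, Picard and MACS2 were used and the genome build was mm9. The notes give no roles or parameters for these tools, and whether domains were called on single or pooled samples is not given in the sources used here. Per the series' design text, input DNA was used in domain calling and reads were then counted in a common set. Reads were single-end, per the labels' protocols, so reads with the same start were not separable into molecules and the intervals of a count cover counting error only. Coordinates are given 1-based on mm9. The gene table at hand is for GRCm38, and 338 domains on 9 chromosomes end beyond its last gene, so no gene names were assigned and the gene lists fixed beforehand were not tested. Domains are named by coordinates alone.

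Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion estimates, TMM factors and the filterByExpr filter by group. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all domains tested, with a threshold of 0.05. The 11 libraries of the tau series and the 12 libraries of the CK-p25 series were fitted apart, since they used different antibody lots, with a mean per group and no other term. Within each model, the contrasts were disease model minus control at each age or time, the average of both, and their difference. The test was repeated on counts summed over the domains with midpoints in each 1 Mb bin. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of F. Levels are TMM-normalised counts (CPM).

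The rule for named domains was set before the data were examined: in each direction, the 10 domains with the smallest adjusted p among those past the threshold with a log2 change of at least 0.3 in size, and for bins the 5 with the smallest adjusted p. The share of reads in the widest 10% of domains, and in the 25% with the fewest other domains within 1 Mb, was computed per library and compared by an exact permutation test with labels exchanged within an age or time. Fold changes of different comparisons were correlated across domains (Spearman's rho), with the other splits of the libraries of either comparison as reference.

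The fits were tested on simulated counts drawn from the real means, library sizes and dispersions. Of 100 domains changed 2-fold, 55 were recovered in the design of tau at 6 months among 43863 domains, and 22 of 100 changed 1.5-fold. At 11 months 62 and 32 were recovered among 43901 domains. For CK-p25 at 2 weeks the numbers were 69 and 36 among 36799 domains, and at 6 weeks 48 and 36 among 36729 domains. Calls on unchanged domains made up 8.33%, 7.84%, 4.55% and 6.67% of all calls in these designs, in the same order. Of 50 simulated bins changed 1.2-fold, 49, 46, 45 and 41 were recovered.

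All 22 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.10 to 1.88 over domains with at least 20 reads in the pair, so no library was counted as a duplicate. The 4 domains on chromosome Y held 332 to 426 reads in each library labelled 11 months, which came from males, and 0 reads in the 17 other libraries, which came from females. A count of 0 allows a share of up to 5.88e-05% to 0.000301% of a library's reads, taking 3 counts as the limit. Labels do not say in so many words that each library is a separate animal, and p-values then measure the spread between these libraries.

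Alternatives were another scaling (DESeq2 size factors, library totals or loess offsets), no filter on low counts, the DESeq2 1.42.0 Wald test, a threshold of 0.01, a replicate block, the cross correlation given in the labels as a covariate, autosomes alone, the compared groups alone, other bin sizes, windows and fractions, and each library left out in turn. Leaving out both shallow 6-week libraries of the CK-p25 series was added after seeing the data. Principal components were those of the log2 CPM (prior count 2) of autosomal domains, within each mouse model.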

Results

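H3K9ac was measured in the hippocampus of 2 mouse models of neurodegeneration. Mice with the P301S mutation of human tau (MAPT), a model of tau aggregation, were compared with wild type mice at 6 months (2 tau and 3 wild type libraries) and 11 months (3 and 3). The younger mice were females and the older ones males, so age and sex changed together. In CK-p25 mice p25, an activator of the kinase Cdk5, can be switched on in forebrain neurons. They were compared with CK controls 2 and 6 weeks after induction, with 3 libraries per group. At these times the mice were 3.5 and 4.5 months old, so age and time after induction changed together. The question was where H3K9ac differs between diseased and control mice.

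The 44165 domains had a median width of 776 bp (quartiles 378 and 1684 bp) and covered 53.3 Mb. Total reads in domains were 4.10 to 6.18 M per library in the tau series and 0.996 to 4.13 M in the CK-p25 series. Cross correlation, a measure of ChIP enrichment given in the labels, was 0.228 ± 0.0263 (SD, n = 3) in tau and 0.313 ± 0.0250 (n = 3) in wild type libraries at 11 months, with no overlap. At 6 months it was 0.243 ± 0.0164 (n = 2) and 0.245 ± 0.00303 (n = 3). In the CK-p25 series it was higher in CK-p25 than in CK libraries on average, at 0.167 against 0.138 at 2 weeks and 0.131 against 0.0928 at 6 weeks.

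At 6 months no domain differed between tau and wild type mice. In edgeR's test 0 of 44105 domains passed, DESeq2 also gave 0, and 1426 domains (3.23%) had an unadjusted p under 0.05. The same held for regions, with 0 of 2279 bins of 1 Mb past the threshold and 64 at an unadjusted p under 0.05. The median standard error of a log2 fold change was 0.26, and of simulated domains changed 1.5-fold in this design 22 of 100 were recovered. Without replicate 1 of the tau group, 8 domains and 2 bins passed.

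At 11 months H3K9ac differed between tau and wild type mice at 5273 of 44105 domains, of which 1940 were higher and 3333 lower in tau mice. The domain on chromosome 9 from 106554205 to 106560104 fell from 110 ± 11.0 CPM (SD, n = 3) in wild type to 50.1 ± 5.14 CPM (n = 3) in tau mice, a log2 change of -1.14 ± 0.08 (SE; edgeR adjusted p = 3.93e-18). On chromosome 2, the domain from 28061404 to 28068757 fell by 1.01 on the log2 scale, and on chromosome 9 the 9607 bp domain from 58043494 to 58053100 fell by 0.84. The largest evidence for a gain was on chromosome 10 from 79535676 to 79539111, which rose from 24.9 ± 2.25 to 62.5 ± 9.10 CPM (n = 3 each; log2 1.33 ± 0.10, edgeR adjusted p = 6.75e-17). Further gains were 1.48 on chromosome 11 (86398403 to 86401198), 1.32 on chromosome 15 (74761667 to 74764197) and 2.16 on chromosome 17 (34879601 to 34880286), all log2.

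**Figure D1:**
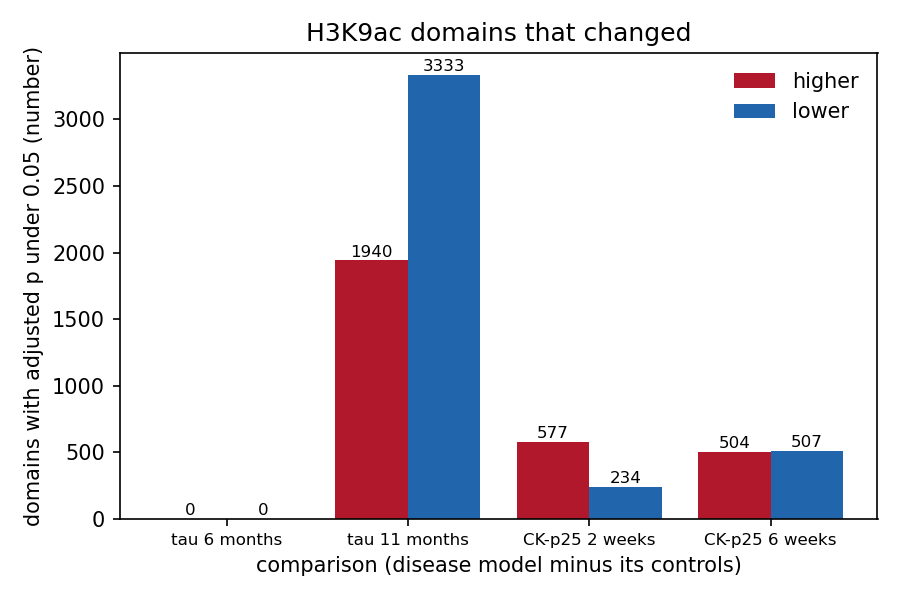
Number of domains (vertical axis) higher or lower in the disease model at an edgeR adjusted p under 0.05, for each of the 4 comparisons (horizontal axis). The bars stand at 0 for tau at 6 months and reach 1940 higher and 3333 lower domains at 11 months.

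Losses at 11 months lay mainly in broad domains. Of the 11041 widest domains (1684 bp or more), 2044 (18.5%) were lower and 733 (6.64%) higher, while of the 10982 narrowest tested domains 151 (1.37%) were lower and 192 (1.75%) higher. Broad domains hold more reads, which eases detection. The split of calls moved with the scaling: with library totals in place of TMM, 2705 domains were higher and 2775 lower. With cross correlation as a covariate, 695 domains passed, and without tau replicate 3, 3452 did. The DESeq2 Wald test called 2909.

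Reads summed over bins of 1 Mb differed at 11 months as well. Of 2279 bins, 404 were higher and 532 lower in tau mice. A bin can pass through a few of its domains, and whether bins changed beyond their called domains was not tested. The strongest gain in evidence was on chromosome 7 from 111 to 112 Mb, where 7 of 8 domains were called higher, the other having the same sign, and the summed reads rose by 1.10 ± 0.12 on the log2 scale (SE; edgeR adjusted p = 1.47e-07). Chromosome 9 from 116 to 117 Mb rose by 0.65. The strongest loss was on chromosome 5 from 132 to 133 Mb, at -0.65 ± 0.05 (edgeR adjusted p = 1.47e-10), with 4 of 11 domains called lower and 9 of negative sign, and chromosome 11 from 56 to 57 Mb fell by 0.73. With DESeq2 size factors of the domain counts the split was 209 higher and 690 lower, and with cross correlation as a covariate 157 bins passed.

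The effect of tau differed between the ages at 1864 domains, 448 of them more positive and 1416 more negative at 11 months, in edgeR's test of the difference. Averaged over both ages, 2017 domains passed (474 higher, 1543 lower). With cross correlation as a covariate these numbers were 412 and 351. At 6 months taken alone 0 domains passed. The average can thus pass through 11 months alone and does not show a change at both ages. Without tau replicate 1 at 6 months, 949 domains differed between ages, and without tau replicate 2 at 6 months, 923 passed on average.

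In CK-p25 mice 2 weeks after induction, gains outnumbered losses: 577 domains were higher and 234 lower than in CK mice, of 38193 tested. The domain on chromosome 16 from 23609351 to 23612236 rose from 18.4 ± 1.08 to 101 ± 18.9 CPM (SD, n = 3 each), which is 5.36-fold (log2 2.42 ± 0.13 SE; edgeR adjusted p = 1.17e-32). A 5.02-fold gain was measured on chromosome 5 (115346882 to 115348607), and gains of 4.21-fold and 3.72-fold on chromosome 19 (12535693 to 12538254 and 34714541 to 34715995). Among called domains losses were smaller, with a median log2 change of -0.39 against 1.09 for gains. The leading loss was on chromosome 19 from 10528976 to 10531855, from 63.5 ± 6.06 to 35.4 ± 3.18 CPM (log2 -0.81 ± 0.12, edgeR adjusted p = 2.43e-07). Of the 234 losses, 212 were among the 11040 tested domains of the widest 25% of the set (1684 bp or more), as were 218 of the 577 gains. Broad domains hold more reads, which eases the detection of small changes. The gap in size between gains and losses may thus partly follow detection.

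Among 1 Mb bins at 2 weeks, 59 were higher and 24 lower of 2266. The bins with the strongest evidence were chromosome 7 from 111 to 112 Mb (log2 1.45 ± 0.13, 6 of 8 domains called higher), chromosome 9 from 116 to 117 Mb (0.91) and chromosome 19 from 34 to 35 Mb (0.41, 9 of 22 domains called higher and 18 of positive sign). The DESeq2 Wald test called 301 domains, and without CK replicate 2, CK-p25 replicate 2 or CK-p25 replicate 3, 419, 422 and 501 passed. With DESeq2 size factors of the domain counts, 32 bins were higher and 27 lower, and leaving out CK replicate 1, 2 or 3 or CK-p25 replicate 2 or 3 left 53, 24, 28, 23 and 24 bins.

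At 6 weeks 504 domains were higher and 507 lower in CK-p25 mice, of 38193. The split moved to 549 higher and 431 lower with library totals in place of TMM, and to 298 and 180 without CK-p25 replicate 1. It moved the other way, to 490 higher and 591 lower, without CK-p25 replicate 2, and to 556 and 630 with a replicate block. The domain on chromosome 16 from 23609351 to 23612236 again led, at 22.6 ± 2.84 CPM in CK and 79.8 ± 5.38 CPM in CK-p25 mice (SD, n = 3 each; log2 1.77 ± 0.14, edgeR adjusted p = 3.46e-18). The largest fold among the named gains was 5.92, on chromosome 13 from 37437294 to 37438908. It rests on a low control level, 3.04 ± 1.75 CPM in CK against 21.6 ± 2.62 CPM in CK-p25 mice (log2 2.56 ± 0.30). The leading loss was on chromosome 13 from 36821380 to 36828820, from 203 ± 24.9 to 128 ± 14.1 CPM (log2 -0.61 ± 0.09, edgeR adjusted p = 1.03e-06). Of the 507 losses, 433 were among the 11040 widest domains, as were 232 of the 504 gains. Of 2266 bins, 126 were higher and 143 lower, led by chromosome 7 from 111 to 112 Mb (log2 1.09 ± 0.14).

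The libraries of lowest depth in the CK-p25 series, CK replicate 3 (0.996 M reads) and CK-p25 replicate 3 (1.31 M) at 6 weeks, stood apart from the rest on the first principal component (23.6% of variance), at 101 and -50.9. Without both, an alternative chosen after seeing the data, 400 domains (232 higher, 168 lower) and 66 bins passed at 6 weeks, and 1796 domains on average over both times. The DESeq2 Wald test called 455 domains at 6 weeks, and without CK replicate 2, CK replicate 3 or CK-p25 replicate 1, 540, 642 and 478 passed. With DESeq2 size factors of the domain counts, 76 bins were higher and 216 lower. Leaving out CK replicate 2 or 3 or CK-p25 replicate 1 or 3 left 119, 140, 107 and 138 bins.

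**Figure D2:**
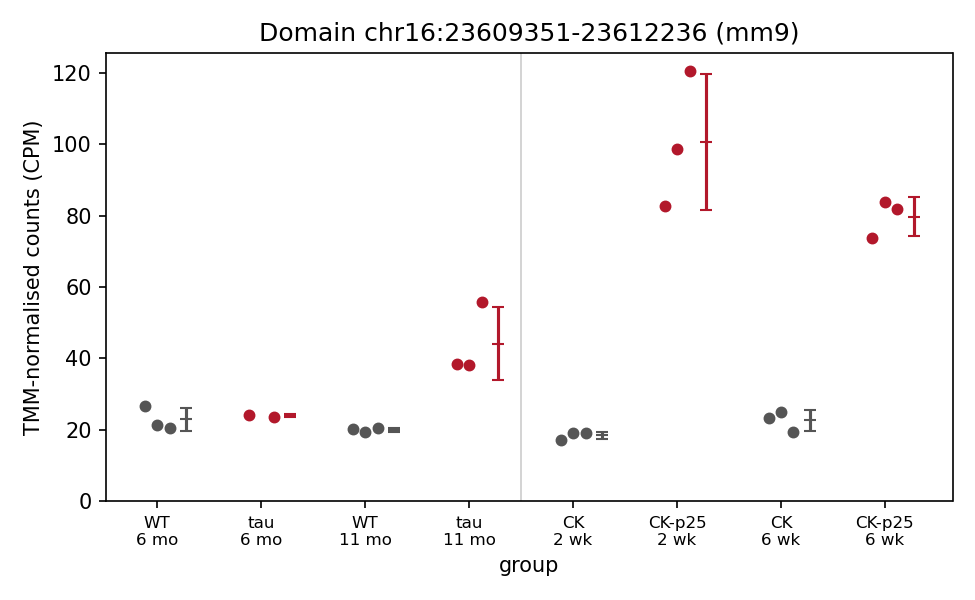
TMM-normalised counts (CPM, vertical axis) in the domain on chromosome 16 from 23609351 to 23612236 in each library (points), by group (horizontal axis). Bars beside the points give the mean and SD. The mean was 101 in CK-p25 and 18.4 in CK mice at 2 weeks, and 44.2 in tau mice at 11 months.

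Between 2 and 6 weeks the effect of p25 differed at 2 of 38193 domains in edgeR's test, against 1817 at an unadjusted p under 0.05 and 0 in DESeq2. The domain on chromosome 10 from 99062373 to 99063196 was at a log2 change of 1.14 ± 0.23 (SE) at 2 weeks and -0.72 ± 0.24 at 6 weeks (adjusted p of the difference 0.00762, edgeR). In CK controls alone this domain was higher at 6 than at 2 weeks, by 1.21 on the log2 scale (edgeR adjusted p = 0.126). The difference thus includes a shift of the controls, which did not pass the threshold by itself. The other lay on chromosome 12 from 73333955 to 73338359, at 0.04 ± 0.09 and -0.62 ± 0.10 (edgeR adjusted p = 0.0372). Leaving out single libraries gave 0 to 8 domains. Averaged over both times, 1221 domains were higher and 1050 lower in CK-p25 mice.

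The share of reads in the widest 10% of domains (2666 bp or more) was lower in CK-p25 mice at both times. It was 40.3% ± 0.401 (SD, n = 3) against 41.1% ± 0.164 (n = 3) at 2 weeks and 39.9% ± 0.316 against 40.9% ± 0.142 at 6 weeks. The mean difference was -0.934 percentage points (exact permutation test, two-sided, p = 0.005, the smallest that 400 arrangements can give). In tau mice it was 38.1% ± 0.368 against 39.7% ± 0.394 in wild type mice at 11 months (n = 3 each), a difference of -1.58 points at the smallest exact p possible, 0.1. At 6 months the difference was 0.119 points, and over both ages the test did not pass (exact permutation p = 0.085). The share in the 25% of domains with the fewest neighbours was lower in tau mice over both ages (difference -0.290 points, exact permutation p = 0.02; p = 0.05 without wild type replicate 2 at 11 months). By age it was -0.460 points at 11 months (exact permutation p = 0.1, the smallest possible) and -0.120 at 6 months (exact permutation p = 0.4), where the groups overlapped. In CK-p25 mice the difference was -0.361 points (exact permutation p = 0.07), with -0.0786 at 2 weeks and -0.643 at 6 weeks (exact permutation p = 0.6 and 0.1). Without CK-p25 replicate 3 at 2 weeks it was -0.443 (exact permutation p = 0.025).

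**Figure D3:**
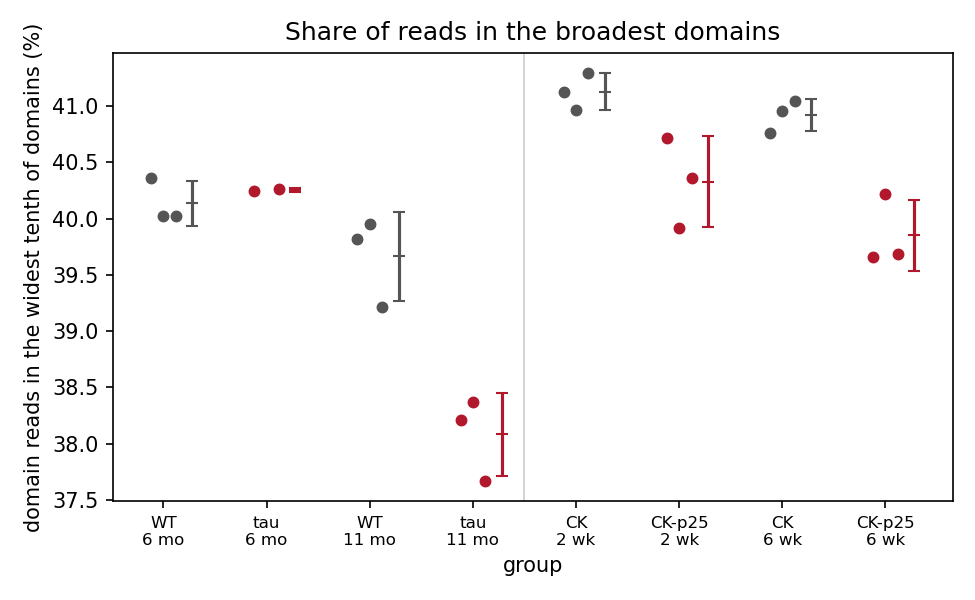
Percentage of each library's domain reads that fall in the widest 10% of domains (vertical axis, not starting at 0), by group (horizontal axis). Points are libraries, and bars beside them give the mean and SD. CK-p25 means of 40.3% and 39.9% lie below CK means of 41.1% and 40.9%.

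Changed domains of the models overlapped in the same direction. Of 570 domains higher in CK-p25 mice at 2 weeks and tested in both series, 375 were also higher in tau mice at 11 months, where independent lists would share 27.7, and 3 were lower. Of 234 lower at 2 weeks, 218 were lower in tau mice at 11 months (19.9 for independent lists) and 0 higher. At 6 weeks 356 of 501 gains and 442 of 507 losses were shared with tau mice at 11 months, against 24.4 and 43.0 for independent lists, and 0 went in opposite directions. Counts for independent lists treat all domains alike. Losses of both models lay mainly in broad domains, so more shared losses than these counts are to be expected. Of the 1858 gains and 3239 losses of tau mice at 11 months among domains tested in both series, most were not called in CK-p25 mice at either time taken alone. In all, 231 domains were higher and 115 lower in tau mice at 11 months and at both CK-p25 times. These comparisons have no library in common.

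Across domains, which are not independent replicates, Spearman's rho between the fold changes of tau at 11 months and CK-p25 was 0.319 at 2 weeks and 0.379 at 6 weeks. Other splits of the libraries of either comparison gave up to 0.283 and 0.306 in size. With 3 libraries per group, every other split holds most libraries of a group on the same side. Each thus keeps part of the real contrast, and these values are not a pure chance level. Between CK-p25 at 2 and 6 weeks rho was 0.260, against up to 0.227. Each set of libraries has 10 splits, so the share of splits as large cannot go below 0.1. Tau at 6 months had a rho of 0.0151 with tau at 11 months, -0.0184 with CK-p25 at 2 weeks and -0.00863 at 6 weeks, all within the range of other splits.

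**Figure D4:**
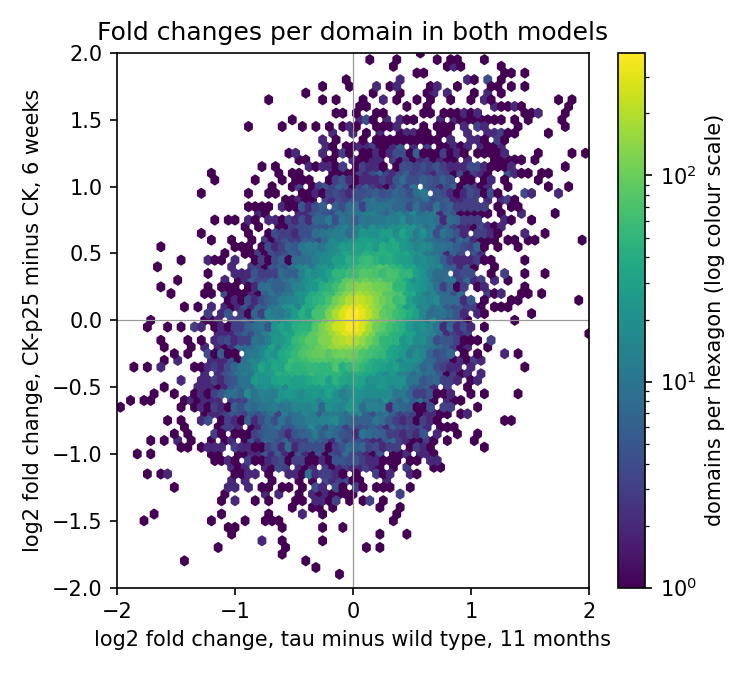
Log2 fold change per domain for tau minus wild type at 11 months (horizontal axis) and CK-p25 minus CK at 6 weeks (vertical axis). Colour gives the number of domains per hexagon on a log scale, and domains beyond 2 in either direction are not drawn. Spearman's rho over 38167 domains was 0.379.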

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

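The counts of other splits below, and the test of direction across models, were set out after the results they bear on had been seen.

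The effect of tau differed between 6 and 11 months at 1864 domains, by edgeR's test of the difference itself. Age and sex changed together between these groups, so neither can be named as what the difference follows. Of 100 splits of the libraries within each age, drawn from 200, 5 gave as many domains, the real one included, with up to 2273 in another split, so chance is not excluded by this count. Of the average over both ages (2017 domains) 5 of 100 splits gave as many, with up to 2577. In both cases the 4 other splits as large kept the real grouping at 11 months. They thus hold the effect at 11 months itself, so these counts cannot decide for or against chance. A first draw held 60 of these splits, of which 4 gave as many for the average and 5 for the difference. It was extended to 100 after these counts were seen.

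The effect of p25 differed between 2 and 6 weeks at 2 domains. Of 100 splits, 19 gave as many and another split gave 590, so chance is not excluded. Of the others as large, 11 kept the real grouping at one of the times, which moves the p25 effect itself into the difference. For the CK-p25 effect averaged over both times, 2271 domains passed. Of 100 splits drawn from 200, 1, the real one, gave as many, and the highest other gave 590. This share is under 0.05, in a count set out after the results were seen. In the first draw of 60 splits, 1 gave as many for the average and 12 for the difference.

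Within a single age or time there are 10 splits, too few for a share under 0.05. At 6 months, where 0 domains and 0 bins passed, all 10 splits gave as many and another split gave 2 domains. In the 3 other comparisons 1 of 10, the real one, gave as many. At 11 months the real split gave 5273 domains and 936 bins, the highest other 1 and 1. At 2 weeks these were 811 and 83 against 5 and 0, and at 6 weeks 1011 and 269 against 19 and 1.

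At 11 months all tau libraries had lower cross correlation than all wild type libraries, so ChIP quality is a candidate explanation of the changes. The effect of cross correlation was estimated within groups and multiplied by the group difference of -0.0859. Its rho with the fold changes of the 5273 domains was -0.0291, where quality as the cause was predicted to give a high positive value. This effect rests on the spread within groups of 2 or 3 libraries. A low rho could come from noise in it and is no evidence against quality. With the covariate, the median size of these changes went from 0.57 to 0.53 and their median standard error from 0.12 to 0.26, so most calls ended through the wider error. Since 3 domains had a covariate effect of their own in edgeR's test and the groups do not overlap in cross correlation, the kept size is no evidence against quality. Cross correlation was higher, not lower, in CK-p25 than in CK mice on average, yet fold changes of tau at 11 months and CK-p25 were positively correlated across domains, with a rho of 0.319 at 2 weeks and 0.379 at 6 weeks, and 0.243 and 0.260 with the covariate in both fits, for which no other splits were run. In the CK-p25 series cross correlation broadly rose with reads in domains. It went from 0.064 in CK replicate 3 at 6 weeks (0.996 M) to 0.187 in CK-p25 replicate 1 at 2 weeks (4.13 M). Its higher mean in CK-p25 mice may thus follow depth, so these rho values cannot decide whether quality is the cause. Libraries of 6 months had a cross correlation of 0.231 to 0.254, within the 0.206 to 0.257 of tau libraries at 11 months. On the first principal component of the tau series (25.1% of variance) they lay at -25.4 to -16.3. Wild type libraries at 11 months lay at -23.9 to -7.73 and tau libraries of that age at 38.1 to 64.5. This argues against low cross correlation alone as the source of that separation, though the 6-month mice also differ in age and sex. Quality differences that cross correlation does not measure, and cell composition, were not tested and stay open.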

How the results depend on the processing

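All alternatives except the next were set before the data were examined. An alternative chosen after seeing the data left out both shallow 6-week libraries (replicate 3 of CK and of CK-p25): 400 domains and 66 bins passed at 6 weeks and 0 domains for the time difference, all weaker, with fewer samples. Of the named domains, none lost its call or direction under any alternative, and among named bins 15 calls, all of losses at 2 weeks, were lost with a library left out. A threshold of 0.01 left 3232 domains for tau at 11 months, 472 and 476 for CK-p25 at 2 and 6 weeks, 1122 and 1368 for the tau and CK-p25 averages, 1037 for the age difference and 1 for the time difference, by construction. The DESeq2 Wald test gave 2909, 301, 455, 1091, 1167, 999 and 0 in that order. The cause was not tested.

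With cross correlation as a covariate, 695 domains passed for tau at 11 months, where standard errors widened, and 157 bins, with 351 domains for the tau average, 412 for the age difference and 1 for the time difference. With only the compared groups fitted, 2 domains passed for tau at 6 months. Bins of 250 kb gave 2119, 264 and 515 calls for tau at 11 months and CK-p25 at 2 and 6 weeks, and bins of 5 Mb gave 280, 5 and 90, as their number changes. In the poorest 10% of domains by density the CK-p25 share differed by -0.321 points (exact permutation p = 0.02). Among domains above the median abundance, rho between the CK-p25 times was 0.408. The cause was not tested.

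Deviations of same-numbered libraries from their group means were weakly correlated (-0.0119 to 0.0516), which cannot settle whether the numbers pair samples. At 11 months every tau library correlated best with its own number, a hint at most, and in CK-p25 mice not every library did. With the replicate block, 1 domain passed for tau at 6 months, 5428 at 11 months, 934 and 1186 for CK-p25 at 2 and 6 weeks, and 5 for the time difference. The other counts stayed within 1.5 times.

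Leaving out each library in turn gave these ranges of changed domains: 0 to 8 for tau at 6 months, 3452 to 5894 at 11 months, 419 to 979 and 478 to 1081 for CK-p25 at 2 and 6 weeks, 923 to 2689 for the tau average, 949 to 2572 for the age difference and 0 to 8 for the time difference. Bins ranged from 0 to 2 at 6 months, 23 to 94 at 2 weeks and 107 to 358 at 6 weeks. Shares in domain-poor regions ranged from -0.348 to -0.235 points in tau and -0.447 to -0.268 in CK-p25 mice. Where 1 tau library is left at 6 months, it is assumed to vary like the other groups. Alternatives for gene lists were not run.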

Other observations

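The tests of the score, of the width and abundance trend and of adjacent bins were set out before their results were seen, and the comparison of control groups was chosen after seeing the data.

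Domains changed in CK-p25 mice were used to score the tau series, as the mean log2 CPM of 1211 domains higher in CK-p25 mice on average less that of 1050 lower ones. At 11 months the score was -1.16 ± 0.31 (SD, n = 3) in tau and -2.26 ± 0.08 (n = 3) in wild type mice, a difference of 1.10 at the smallest exact permutation p possible, 0.1. At 6 months it was -2.21 ± 0.08 (n = 2) and -2.19 ± 0.06 (n = 3), a difference of -0.0205, below the 0.109 of another split (exact permutation p = 0.7). The hypothesis that the domains changed in CK-p25 mice were already shifted in tau mice at 6 months had no backing in these libraries.

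Tau libraries at 11 months were spread along this score, at -1.10, -1.50 and -0.88, more than any other group of the tau series. A trend of fold change with domain width and abundance, shared by both models, is a candidate explanation for their concordance. After removal of the median fold of domains of like width and abundance, rho with CK-p25 was 0.311 at 2 weeks and 0.374 at 6 weeks, above the highest of other splits treated alike at each time (0.279 at 2 weeks), which argues against that trend as the whole cause. A change in the mix of cell types common to both models stays open, since no domain could be tied to a gene.

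Changes may extend beyond 1 Mb. Here the fold change of a bin was the unweighted mean of the log2 fold changes of its domains, not that of the summed reads. The rank correlation of these values between adjacent 1 Mb bins was above the highest of the other splits in 1 of the 4 comparisons, CK-p25 at 6 weeks (0.132 against 0.106). For tau at 11 months it was 0.107 against 0.134, and at 2 weeks 0.0420 against 0.0700. Between bins 2 Mb apart no comparison was above the highest other split, and 5 Mb apart tau at 11 months was (0.0305 against 0.0224). These values go both ways, so whether changes extend beyond 1 Mb cannot be told apart from the structure of other splits.

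Wild type mice differed between 11 months (males) and 6 months (females) at 423 domains higher and 215 lower in edgeR's test, of which 411 and 172 were autosomal. Cross correlation did not overlap between these groups either (0.296 to 0.342 at 11 months, 0.242 to 0.248 at 6 months). Age, sex and ChIP quality therefore cannot be told apart here. On chromosome 8 from 19784019 to 19785412 the log2 change was 1.22 (edgeR adjusted p = 2.18e-21). CK mice differed between 6 and 2 weeks at 1 domain.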
